A study of Homo sapiens with 40 samples.

How the data were processed

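The samples were blood cells of 16 people with acute HIV-1 infection, named participants A to P in the labels. They were measured by droplet-based single-cell RNA sequencing of transcript 5-prime ends on Chromium Next GEM chips, per the labels' protocols. Peripheral blood mononuclear cells (PBMC) of 14 participants, A to N, made up 24 libraries. Participants A to H were run on a first chip and I to N on a second chip, with 1 library each except for F. Participant F had 11 libraries, of which 1 was on the first chip, 2 on the second and 8 on another. Sorted CD4+ T cells gave 14 libraries, 7 each from participants O and P. A sort of T cells with neither CD4 nor CD8 at the surface, called CD4-CD8- here, gave 1 library from O. A further library of P was in no group, because its title names the CD4-CD8- sort and its tissue field CD4+ T cells. Groups came from the tissue label. The labels state 21000 cells loaded per PBMC well and per sorted well of O, and 14000 to 21000 per sorted well of P. They give no viral load and no outcome, and no uninfected people were among the samples.

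The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs, 1 per captured RNA molecule) per gene and cell barcode, not normalized, per the file headers and the values. Cell Ranger and the genome build GRCh38 are named per the submitters' processing notes, and the matrix headers give software version 3.1.0. The gene annotation release was not given in the sources used here. Each matrix lists 36602 features, of which 36601 are human and 1 is named HIV. The sequence behind the HIV feature was not given in the sources used here, so a virus whose RNA differs from it would be counted less fully. Gene positions came from GENCODE release 29 on GRCh38, where 34616 of the feature IDs were found. Counts of genes that overlap or have near-identical copies depend on how the upstream counting assigned them.

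From the 275575 barcodes, those with at least 300 detected genes and at most 10% mitochondrial UMIs were kept. Scrublet, as run in scanpy 1.11.5, was the planned doublet caller with an expected rate of 0.07. Its automatic threshold marked under 0.5% of barcodes in 33 of 40 libraries, and in 24 of the 29 largest, so it was not used. The top share of Scrublet scores, at that rate of 0.07, was removed from each library instead, and the automatic threshold was kept as an alternative. After all filters 223475 cells remained. Cells were log-normalized to 10000 UMIs and clustered on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, with at most 2000 cells per participant. The remaining cells took the majority cluster of their 15 nearest clustered cells. PBMC and sorted libraries were clustered separately. Genes of the fixed lists and sex-linked, HLA, immunoglobulin, T cell receptor, ribosomal and mitochondrial genes did not enter the clustering. Clusters were named from 17 fixed marker sets, and each class name means cells like that type. In the sorted libraries, the clusters called CD4 T clusters here took their name from the CD4+ gate, not from markers. Clusters led by naive or regulatory T cell markers were placed with the CD4 T or CD8 T class whose markers they held. Any other cluster with too few markers, or with a low UMI count and none of its own markers, stayed unnamed. The marker sets of gamma-delta T cells, progenitors and neutrophils named no PBMC cluster.

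UMI counts were summed per participant or library and class where at least 50 cells were present. Differences between participants were tested per class in CD4 T, CD8 T, NK, B and CD14 monocyte cells with the quasi-likelihood F test of edgeR 4.0.16 (TMM normalization, filterByExpr). Only the 11 libraries of F gave residual spread in that test. CD4 T and CD8 T cells came from the same blood sample of each person, so participant was a block in their edgeR test. The comparison of CD4 T cells with and without HIV RNA used the same test and block in F, O and P, the participants with at least 20 positive cells. Adjusted p-values are Benjamini-Hochberg values, with 0.05 as the threshold. Competitive list tests used camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. The alternative was fry, which tests a list without setting it against other genes. Between CD4 T and CD8 T cells, genes used in clustering or as markers were in the fit but were not counted. The p-values were adjusted over the other genes. The sorted CD4-CD8- library had no replicate, so CPM ratios carry exact conditional binomial intervals, and list medians were ranked among 10000 random lists of the same size matched on mean expression.

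The 12 lists fixed in advance were interferon-stimulated genes, interferon-gamma response, cell cycle, cytotoxicity, activation and checkpoint, HLA class II presentation, HIV entry and dependency, HIV restriction, inflammatory cytokines and chemokines, immediate early and heat shock, apoptosis and cell death, and type I and III interferon ligands. A list score is the mean over detected members of log2(CPM + 1) of the summed counts, with TMM scaling. Class comparisons and correlations used counts summed per participant, while ranges and SDs set beside the libraries of F used scores per library, so the same score differs a little between them. On this scale changes of low genes are understated. Paired scores were compared with two-sided exact sign-flip permutation tests. Correlations were tested by two-sided permutation tests with 100000 resamples. The planned test of the spread of cell shares between people against that between libraries of F is not given, because it sets single samples against repeat captures. List membership among called genes used a two-sided Fisher's exact test. The lists, groups, tests and naming rule were chosen before the data were examined, apart from what is said below.

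Genes were named by rule. Between CD4 T and CD8 T cells these were the 12 most positive and 12 most negative fold changes past the threshold, with an average log2 CPM of at least 5 and the same direction in at least 13 of 14 participants. Between participants they were the 6 genes of largest SD per class, and in the sorted libraries the 12 highest and 12 lowest ratios among genes of at least 20 CPM on 1 side and 50 UMIs in both together. Up to 4 members per list were added. The fixed rule did not cover the HIV comparison, where the rule for CD4 T and CD8 T cells was used after the data were seen, with the direction shared by all 3 participants. Ribosomal, mitochondrial and uncharacterised genes were counted, not named. Some genes that the rule selects are not reported here. In all, 828 features were left out of tests, among them sex-linked, HLA, KIR, immunoglobulin and T cell receptor genes. The 6 genes of the HLA class II list were kept. Values of a single gene over the participants are given only as a mean, fold change, range or SD.

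Shares of cells with HIV RNA have exact Clopper-Pearson 95% intervals, and a count of 0 is given the limit that 3 counts allow. Both cover counting error only. To compare depths, cells were also thinned to 2000 UMIs, leaving out shallower ones. A cell rich in HIV RNA is one with at least 10 HIV UMIs, a limit set after the data were seen.

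Each edgeR test was first run on simulated counts drawn from the real means and library sizes, with 200 genes changed by known folds. The spread between libraries was set in advance, not taken from the data, and the changed genes were picked among better expressed ones. The shares recovered hold for that setting. At log2 changes of 0.5, 1 and 2, edgeR recovered 36.4%, 98.3% and 100% between participants in CD4 T cells (11590 genes) and 38.8%, 93.0% and 100% in CD8 T cells (12807 genes). The shares were 21.5%, 87.9% and 100% in NK cells (9738 genes), 19.3%, 96.6% and 100% in B cells (10441 genes) and 35.5%, 96.5% and 100% in CD14 monocytes (11820 genes). Between CD4 T and CD8 T cells they were 63.8%, 100% and 100% (12771 genes), and between cells with and without HIV RNA 17.5%, 78.6% and 96.9% (13432 genes). Among unchanged genes the simulations called 2 to 10.

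Alternatives covered doublet removal, the gene and mitochondrial filters, Leiden resolutions of 0.5 and 2, normalization, pseudocount, the filter on low counts, DESeq2 1.42.0, chip as a covariate, the participant block, which libraries stood for F, leaving out each participant, and 2 HIV UMIs to mark a cell. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9, and in R 4.3.3. Expression of genes that tell the sexes apart was not reported.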

Results

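Blood cells of 16 people in acute HIV-1 infection were profiled cell by cell, as PBMC in participants A to N and as sorted T cells in O and P. The 24 PBMC libraries held 7154 to 10891 barcodes and 37135586 to 69861590 UMIs each, and 165345 of their 210099 barcodes passed the filters. Of the others, 29058 were removed for mitochondrial UMIs, 3248 for few genes and 12448 as presumed doublets. Median depth per library was 4310.5 to 5404 UMIs and 1516.5 to 1849 genes per cell, with a median of 1.46% to 3.57% mitochondrial UMIs. The 14 libraries of sorted CD4+ T cells held 14069580 to 38450935 UMIs and 54264 cells, with median depths of 4500 to 5927.5 UMIs. The sorted CD4-CD8- library of O held 18899318 UMIs and 3169 cells (median 4922 UMIs). Participant F, with 11 libraries, gave 45.8% of the PBMC kept and served to measure the spread between repeat captures. Libraries of 1 participant are repeat captures of 1 sample, so the participant is the replicate.

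The first question was which blood cells were present and how far people differed. CD8 T cells were the most frequent class at 23.2% ± 8.53 of cells (SD, n = 14 participants), followed by CD14 monocytes at 18.6% ± 9.64 and CD4 T cells at 17.9% ± 8.47. CD4 T cells, the main target of HIV, ranged from 1.33% to 31.2%, and CD8 T cells from 9.97% to 42.1%. CD8 T cells outnumbered CD4 T cells in 11 of 14 participants, with a median CD8 to CD4 ratio of 1.24 and a range of 0.331 to 14.2. A mixed cytotoxic class, holding markers of several killer lymphocytes, made up 9.83% ± 5.58. MAIT cells, which recognise microbial vitamin metabolites, made up 4.55% ± 1.99, NK cells 4.36% ± 1.46 and B cells 4.32% ± 1.87. Cycling T cells averaged 3.63% ± 2.02, CD16 monocytes 3.39% ± 3.26, antibody-secreting plasma cells 2.66% ± 2.59, platelets 1.41% ± 1.39, dendritic cells 0.644% ± 0.446 and erythroid cells 0.195% ± 0.243. The dendritic class split into 414 conventional and 297 plasmacytoid cells, with 39 and 50 cells unnamed.

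The share of CD8 T cells had an SD of 8.53 over participants and 0.808 over the libraries of F. For CD14 monocytes the SDs were 9.64 and 0.393, for CD4 T cells 8.47 and 0.499 and for NK cells 1.46 and 0.190. The libraries of F are repeat captures of 1 sample, so their SD is technical, while that over participants also holds sampling and handling. The unnamed class made up 5.20% ± 4.10 of cells. Its main cluster had a median of 900.5 UMIs, and 74.9% of that cluster came from F. F also held 80.5% of all plasma cells, at 9.96% of its cells.

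**Figure D1:**
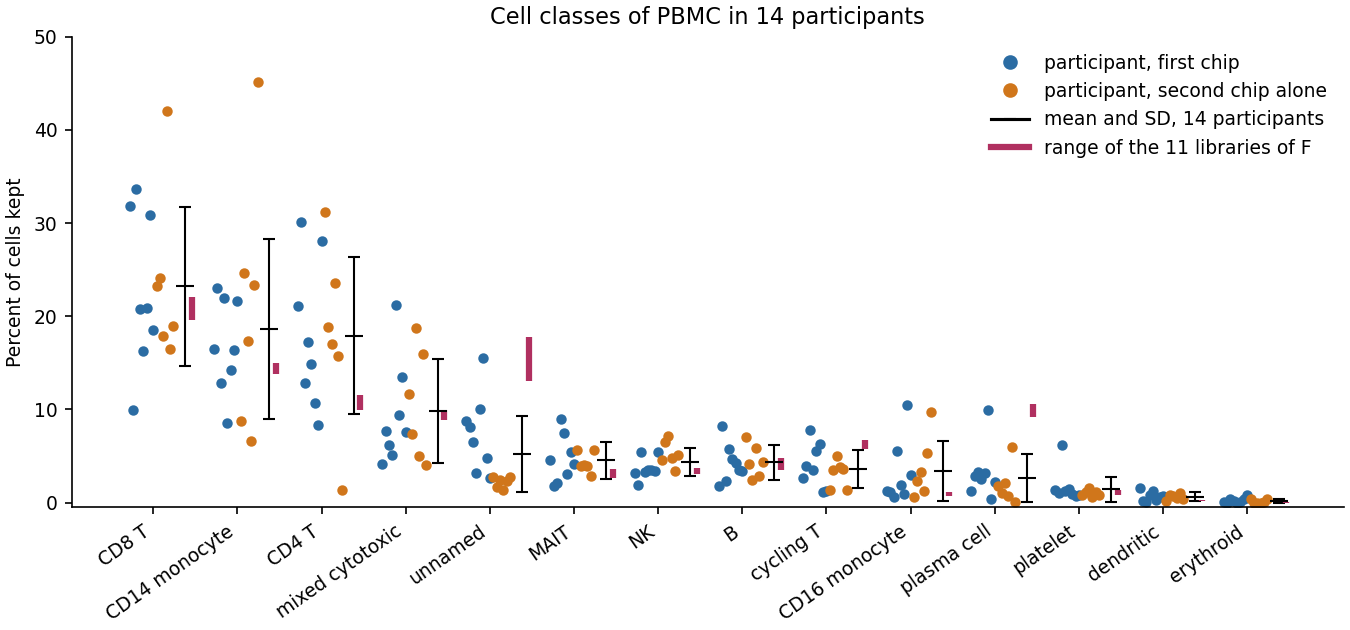
Percent of kept cells in each class, with 1 point per participant coloured by chip, the mean and SD over 14 participants as black lines, and the range over the 11 libraries of F as a bar. CD8 T cells averaged 23.2% and CD4 T cells 17.9%, and the range of F is narrow beside the spread of participants.

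Gene programmes were then compared between cell classes of the same person. Interferon-stimulated genes, the antiviral genes switched on by type I interferon, scored highest in monocytes, at 7.59 ± 0.824 in CD14 monocytes and 7.76 in CD16 monocytes (log2 scale, SD over participants). They scored 6.09 ± 0.925 in CD4 T, 6.12 in CD8 T, 6.18 in NK, 5.90 in B, 5.86 in MAIT and 5.44 in plasma cells. The CD16 monocyte and plasma cell means are over 12 participants and the others over 14, so they do not give the order within people. Within people the difference of CD14 minus CD16 monocytes was positive, and it turned to -0.139 without TMM. Interferon-gamma response genes scored 6.91 in CD14 monocytes and 4.55 in CD4 T cells. CD4 T cells were lower than CD14 monocytes in all 14 participants for both lists, by -1.51 and -2.36 (adjusted p = 0.000441 each, exact sign-flip permutation). The same held for inflammatory cytokines and chemokines (-4.32), HLA class II presentation (-4.63), immediate early and heat shock genes (-1.52) and apoptosis genes (-0.72). Activation and checkpoint genes were higher in CD4 T cells in 14 of 14 participants, by 1.51, and HIV entry and dependency genes by 0.80. Inflammatory genes scored 6.78 ± 2.43 in CD14 and 5.95 ± 2.55 in CD16 monocytes, and 2.22 to 3.08 in the other 6 classes. Within 12 participants with both, the CD14 monocytes were higher by 1.0 (12 of 12, adjusted p = 0.0008, permutation).

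CD8 T cells exceeded CD4 T cells in cytotoxicity genes, which arm cells to kill, with a difference of CD4 T minus CD8 T of -3.75 on the log2 scale (14 of 14 participants, adjusted p = 0.000441, permutation). That difference was -1.46 for HLA class II, -1.15 for cell cycle, -0.37 for apoptosis and -0.31 for interferon-gamma response, each lower in CD4 T cells in 13 of 14 participants (adjusted p = 0.000767, permutation). HIV restriction genes, which block steps of viral replication, differed by -0.14 (14 of 14). Interferon-stimulated genes did not differ detectably (-0.04, adjusted p = 0.485, permutation), nor did HIV entry genes (0.08, adjusted p = 0.157, permutation). The HIV entry list includes CD4, a marker that names the class. Without it the other 17 members had a mean log2 fold change of -0.085 and a median of -0.195, CD4 T minus CD8 T. By edgeR 13 of them were lower in CD4 T cells and 3 higher, with CCR6 at 6.04. MAIT cells had the highest HIV entry score of the 8 classes, 5.99, and exceeded CD4 T cells in 14 of 14 participants (difference of CD4 T minus MAIT -0.20, adjusted p = 0.000441, permutation). Of these 8 classes, which leave out cycling T cells, plasma cells had the highest cell cycle score, 5.96, B cells the highest HLA class II score, 11.34, and NK cells the highest cytotoxicity score, 8.95. Type I and III interferon ligand genes scored from 0.00 in B cells to 0.38 ± 0.577 in CD14 monocytes and 1.02 ± 1.51 in CD16 monocytes, where single participants ranged from 0 to 3.502. In all, 278 of 336 list and class pairs passed the adjusted threshold. The smallest p that 14 sign flips can give is 0.000122. Some small differences turned sign with another scaling or doublet rule: cytotoxicity in CD4 T minus B cells was 0.58 but -0.52 without doublet removal.

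**Figure D2:**
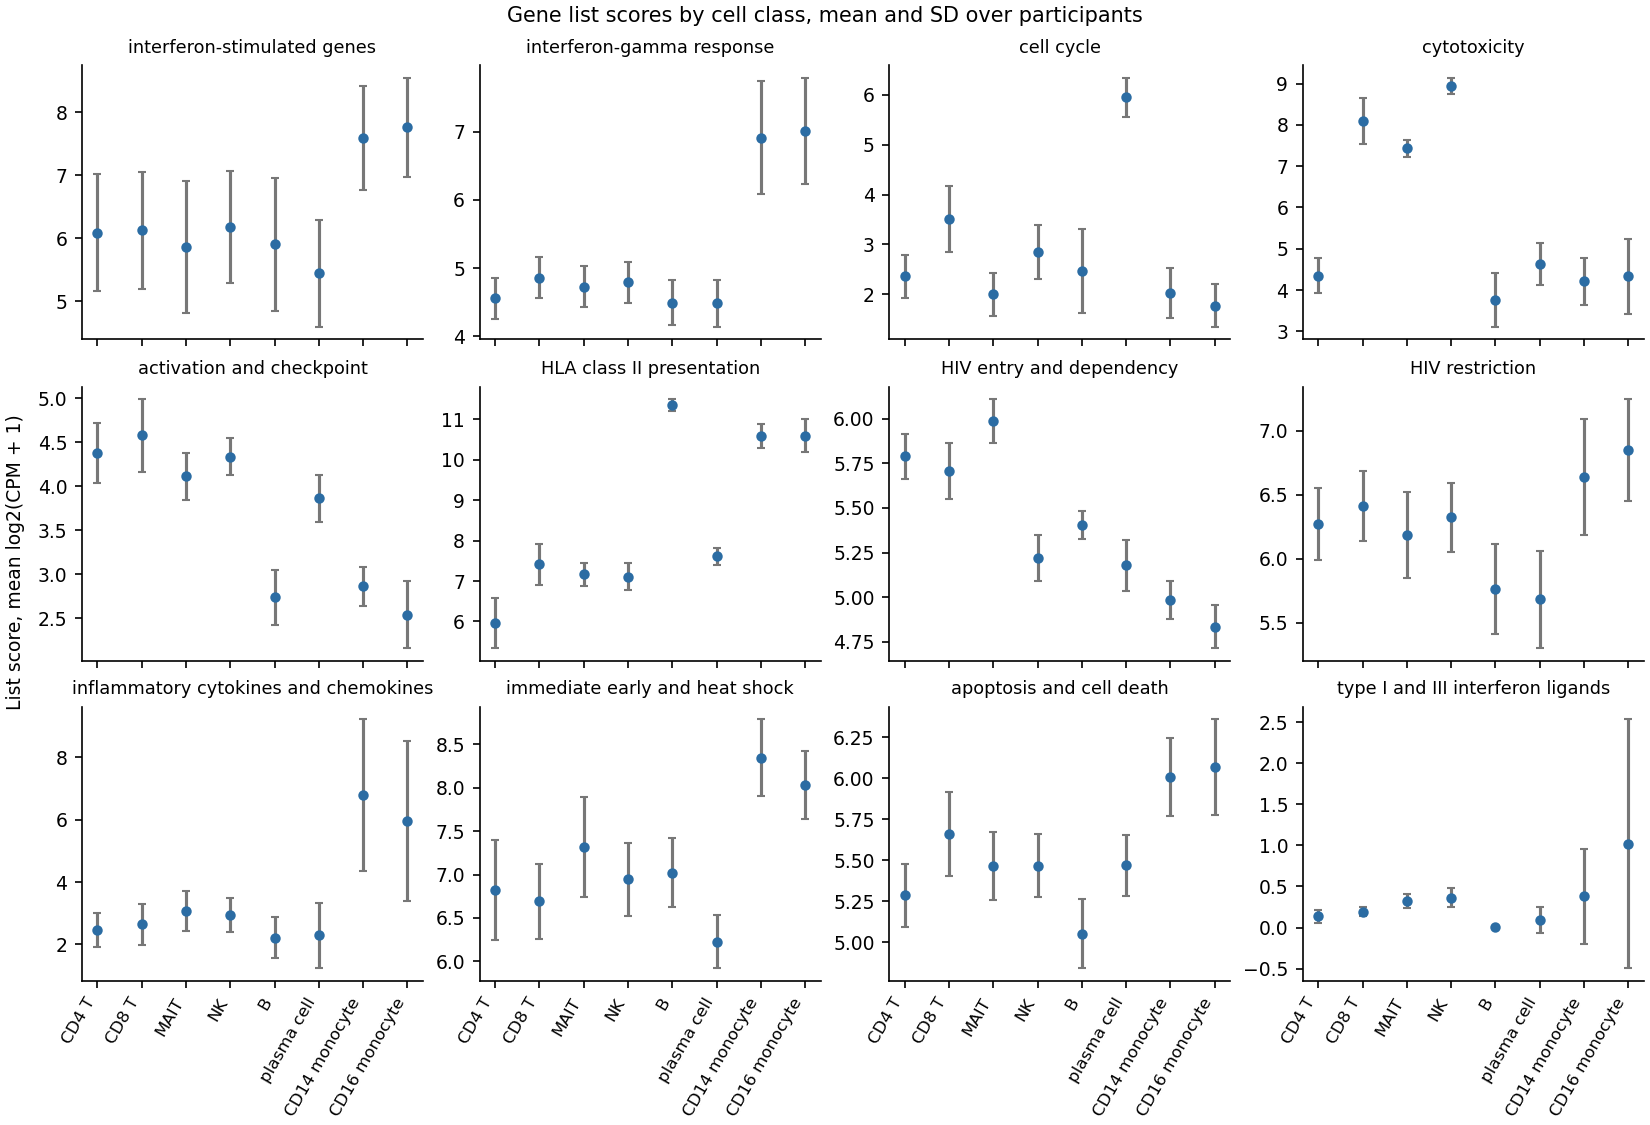
Scores of the 12 gene lists (mean log2(CPM + 1)) in 8 cell classes, as mean and SD over 14 participants (12 for CD16 monocytes and plasma cells). Interferon-stimulated and inflammatory genes are highest in the monocyte classes and cytotoxicity genes in NK and CD8 T cells.

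Interferon-stimulated genes were then compared between the libraries of different people. IFIT1, an interferon-induced protein that binds foreign RNA (ENSG00000185745, GRCh38 chromosome 10, 89392546 to 89406486, plus strand), ranged from 2.33 to 7.87 log2 CPM in CD4 T cells, with an SD of 1.97 over participants and 0.12 over the libraries of F. Its SD was 2.12 in CD8 T, 2.19 in NK and 2.22 in B cells. IFIT3 (SD 1.90), RSAD2 (1.66) and IFI27 (1.48) varied likewise in CD4 T cells, and IFI27 had an SD of 1.79 in CD8 T cells against 0.04 over the libraries of F. All measured members of the list were called in each class, 39 of 39 in CD4 T, CD8 T and CD14 monocytes and 38 of 38 in NK and B cells. The list score ranged from 4.86 to 7.44 in CD4 T cells and from 6.58 to 8.64 in CD14 monocytes. In these 5 classes its SD over participants was 18.3 to 27.4 times that over the libraries of F, and in CD16 monocytes and MAIT cells 10.6 and 12.8 times.

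In CD14 monocytes the gene of largest SD, among those with an average log2 CPM of at least 5, was CCL4, a chemokine, with an SD of 4.56 over participants and 0.35 over the libraries of F. The other chemokines CCL20 (3.99), CCL3 (3.44) and CXCL3 (3.26) and the cytokines IL6 (4.0) and IL1B (3.35) followed, and IL1B ranged from 4.37 to 13.87 log2 CPM. All 18 measured inflammatory genes were called, and their score ranged from 3.76 to 10.95 (SD 2.45 against 0.0887 for F). Different clusters held this class in different people. Cluster 8 held most CD14 monocytes of A, C, D, E and I, cluster 9 those of B, F, G and H, and cluster 19, led by IL1B and CXCL8, at least 90.2% of those of J to N. The immediate early gene FOS had an SD of 1.2 in CD4 T cells. The interferon-inducible restriction factor APOBEC3A had an SD of 1.59 in CD14 monocytes and MX2 of 0.89 in CD4 T cells. In CD8 T cells the SD was 1.08 for MKI67, a marker of dividing cells, 0.93 for the activation marker CD38, 0.90 for PDCD1, 1.2 for CX3CR1 and 0.86 for HLA-DRA. That class pools clusters 1, 3 and 7, and cluster 1 ranged from 2.498% to 28.6% and cluster 7 from 0.766% to 24.2% of the cells of a participant.

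Other genes of largest SD were CISH (1.71) and JCHAIN (1.52) in CD4 T cells, MYOM2 (2.48) and LIM2 (2.15) in CD8 T cells, HBB (3.56), S100B (3.2), MYOM2 (2.01) and LAIR1 (1.80) in NK cells, and HBB (2.91) and OASL (1.99) in B cells. JCHAIN is made by plasma cells, whose share ranged from 0.0161% to 9.96%, and HBB by red cells, whose share ranged from 0% to 0.827%. The edgeR quasi-likelihood test called 7334 of 11978 genes in CD4 T, 10879 of 13276 in CD8 T, 4033 of 10029 in NK, 4931 of 10784 in B and 9911 of 12339 in CD14 monocyte cells (Benjamini-Hochberg adjusted p under the 0.05 threshold). Each participant other than F had 1 library, so the calls say that libraries of different people differed by more than repeat captures of 1 sample, and do not part people from sampling or handling. DESeq2 called 3724, 7610, 1469, 2011 and 6446 genes.

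Other lists were called more often than the genes tested in some classes. In NK cells, where 40.2% of genes were called, all 11 lists were enriched by Fisher's exact test, from interferon-stimulated genes (adjusted p = 4.58e-14) to HLA class II, 6 of 6 (adjusted p = 0.00860). NK cells had calls in 14 of 16 interferon-gamma response, 22 of 26 cell cycle, 16 of 16 cytotoxicity, 12 of 12 activation, 13 of 16 HIV entry, 21 of 26 restriction, 10 of 10 inflammatory, 14 of 15 immediate early and 11 of 13 apoptosis genes. In B cells (45.7% called) all lists but activation (7 of 10) and HIV entry (10 of 16) were enriched. CD4 T cells (61.2% called) were enriched in 8 lists, among them 15 of 15 cytotoxicity and 26 of 28 restriction genes, but not in interferon-gamma response (16 of 19), HLA class II (6 of 6) or apoptosis (11 of 12). In CD8 T cells (81.9% called) interferon-stimulated genes, 30 of 30 cell cycle and 28 of 28 restriction genes passed. In CD14 monocytes (80.3% called) the lists past the threshold were interferon-stimulated, interferon-gamma response (22 of 22), cell cycle (29 of 30) and restriction (27 of 28), while inflammatory genes had an adjusted p of 0.0520. That made 35 of 55 tests, and 54 of 59 without the filter on low counts. Counts adjusted over the list alone exceeded these by at most 2 genes. The background was not matched on expression, and better expressed genes are easier to call. The Fisher tests therefore do not part list membership from expression level.

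Interferon scores rose and fell together across the cell types of a person. The score of CD14 monocytes correlated with that of CD4 T (Pearson r = 0.965, Spearman rho = 0.925), CD8 T (0.972 and 0.952), NK (0.981 and 0.965) and B cells (0.970 and 0.934) over 14 participants. The permutation p for each r was 1e-05, the smallest the permutations can give (adjusted p = 2.75e-05 over 11 relations). The rho values had adjusted p-values of 3.67e-05 to 5.50e-05. Without the 2 farthest participants r was 0.961 to 0.979. Within the 8 participants of the first chip r was 0.981 to 0.995, with exact permutation adjusted p-values up to 0.0017. Within the 6 of the second chip alone r was 0.965 to 0.993, with an exact permutation adjusted p of 0.0178, and rho was 0.8286 to 0.943, with adjusted p-values of 0.0612 to 0.107.

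No other relation passed over all participants. Cell cycle scores of the T cell classes leave out the cycling T class, at 1.16% to 7.77% of a participant's cells. Cell cycle scores of CD8 T and CD4 T cells gave r = 0.511 and rho = 0.578 (permutation p = 0.0629 and 0.0338, adjusted p = 0.138 and 0.0744). That r was 0.371 without the 2 farthest, 0.777 on the first chip and -0.247 on the second. CD8 T and NK cell cycle scores gave r = -0.054 and rho = -0.011 (permutation p = 0.855 and 0.977). Interferon score in CD4 T against cell cycle score in CD8 T cells gave r = -0.174 and rho = -0.112 (permutation p = 0.542 and 0.703), and log2 CD8 to CD4 ratio against cell cycle score r = -0.222 and rho = 0.024 (permutation p = 0.467 and 0.939). Without the 2 farthest participants these 3 gave r = -0.169, -0.257 and 0.188. The CD16 share of monocytes against the interferon score of CD14 monocytes gave r = 0.415 and rho = 0.275 (permutation p = 0.133 and 0.341), with r = 0.119 without the 2 farthest, 0.289 on the first chip and 0.952 on the second. The plasmacytoid share, of the cells known to make most type I interferon, against the interferon score of CD4 T cells gave r = 0.122 and rho = 0.336 (permutation p = 0.681 and 0.241). That r was 0.750 without the 2 farthest participants (adjusted p = 0.0157, permutation), where rho was 0.636 (adjusted p = 0.0675). On the first chip r was -0.188, and on the second 0.942 (exact permutation adjusted p = 0.0178) with rho = 0.8286 (adjusted p = 0.107). Inflammatory scores of CD14 monocytes, here of counts summed per participant, fell into separate ranges, 3.73 to 5.96 in A to I and 8.48 to 10.88 in J to N, so no pooled correlation with the interferon score is given. On the first chip it was r = -0.792 and rho = -0.929 (exact permutation p = 0.00546, adjusted p = 0.012). The second chip gave r = 0.874 across that gap, with 1 participant below it and 5 above.

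**Figure D3:**
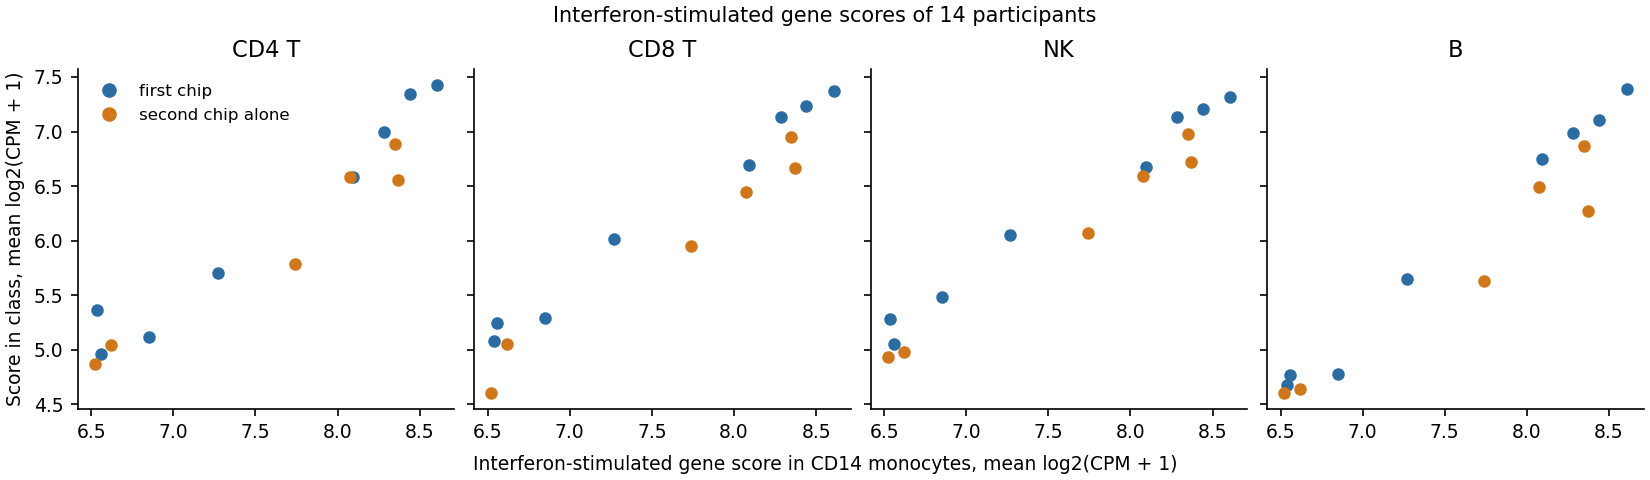
Interferon-stimulated gene score of CD4 T, CD8 T, NK and B cells (vertical, mean log2(CPM + 1)) against the score of CD14 monocytes (horizontal), 1 point per participant (n = 14), coloured by chip. All 4 classes rise with CD14 monocytes (r = 0.965 to 0.981).

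CD4 T and CD8 T cells of the same blood were compared next. Among genes with an average log2 CPM of at least 5, FGFBP2, a protein secreted by killer lymphocytes, was lower in CD4 T cells by a log2 fold change of -6.18 (SE 0.191), followed by granzyme B (GZMB, -5.82, SE 0.191), NKG7 (-5.62), CX3CR1 (-5.17), KLRD1 (-5.10) and perforin (PRF1, -4.36, SE 0.152). C1orf21 (-4.91), ZNF683 (-4.44), CCL4 (-4.41), FGR (-4.27), KLRC4 (-4.18) and SLAMF7 (-4.07) complete the 12 lowest of these. TNFRSF4, the costimulatory receptor OX40, was the most positive of them at 4.44 (SE 0.234, 6.08 against 1.54 log2 CPM). BIRC3 (2.33), LINC02273 (2.06), TCEA3 (1.85), KDSR (1.81), the cytokine signalling inhibitors SOCS3 (1.80) and CISH (1.74), the costimulatory receptor CD28 (1.77), RCAN3 (1.73), SUSD3 (1.61), PLP2 (1.56) and TNFSF8 (1.48) followed. GZMB (ENSG00000100453) lies on GRCh38 chromosome 14, 24630954 to 24634267, minus strand, and TNFRSF4 (ENSG00000186827) on chromosome 1, 1211326 to 1214138, minus strand.

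Among HIV entry genes, the chemokine receptor CCR6 was higher in CD4 T cells by 6.04 (SE 0.147), while CXCR6 (-1.99) and ITGA4 (-0.74) were lower. Of 17 measured entry genes 3 were higher and 13 lower in CD4 T cells. Restriction genes were split, 10 higher and 11 lower of 28, with APOBEC3H (-2.83), APOBEC3G (-1.84), which mutates viral DNA, and APOBEC3C (-1.63) lower and MORC2 higher (1.31). All 16 cytotoxicity genes, all 30 cell cycle genes and all 6 HLA class II genes were lower, among them MKI67 (-2.37), TYMS (-2.54), CDT1 (-2.64), CLSPN (-2.44), HLA-DRA (-2.13) and HLA-DMA (-1.52). The cycling T class was in neither group. Activation genes went both ways, 4 higher and 9 lower of 15, with HAVCR2 (-3.40) and LAG3 (-3.32), receptors that restrain T cells, lower and TNFRSF18 (2.93) higher. Of 19 interferon-gamma response genes 1 was higher, SOCS1 (0.77), and 13 lower, among them CIITA (-1.82), IRF1 (-0.75) and GBP5 (-0.73). Interferon-stimulated genes had 11 higher and 11 lower of 39 (median 0.01, mean -0.05), with IFI27 (-1.38) and OASL (-1.18) lower and LGALS3BP (0.89) and IFI44L (0.80) higher. Inflammatory genes had 4 higher and 2 lower of 15 (median 0.10, mean -0.05), CCL20 (2.16) and OSM (1.40) among the higher and CCL3 (-2.63) the lower. Immediate early genes had 5 higher, such as JUNB (0.85) and FOS (0.63), and 3 lower of 15. Apoptosis genes had 3 higher, such as BCL2 (1.17), and 8 lower of 13, such as FASLG (-4.26) and BCL2L11 (-1.21). Of the interferon ligands IFNL1 was tested, at -0.55 (SE 0.27, adjusted p = 0.0856, edgeR).

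The edgeR quasi-likelihood test with participant as a block called 7491 of 11679 genes at the Benjamini-Hochberg threshold, 3755 higher and 3736 lower in CD4 T cells. FGFBP2 had an adjusted p of 4.13e-15 and TNFRSF4 of 7.70e-12. At absolute log2 fold changes of at least 1, 1395 genes remained past the threshold. Adjusted over the list alone, the counts were 4 higher in HIV entry and 12 lower in restriction genes, and the same for the other lists. Camera with the preset correlation gave adjusted p-values of 5.45e-46 for cytotoxicity, 1.49e-12 for cell cycle, 7.10e-05 for HLA class II, 0.000304 for interferon-gamma response and 0.00493 for apoptosis. With an estimated correlation cytotoxicity held (adjusted p = 0.00254), and the other 4 lists had an adjusted p = 0.209. The other 6 lists did not pass with either (preset adjusted p = 0.0916 to 0.906). For interferon-stimulated genes the camera direction was down, against a median of 0.01.

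**Figure D4:**
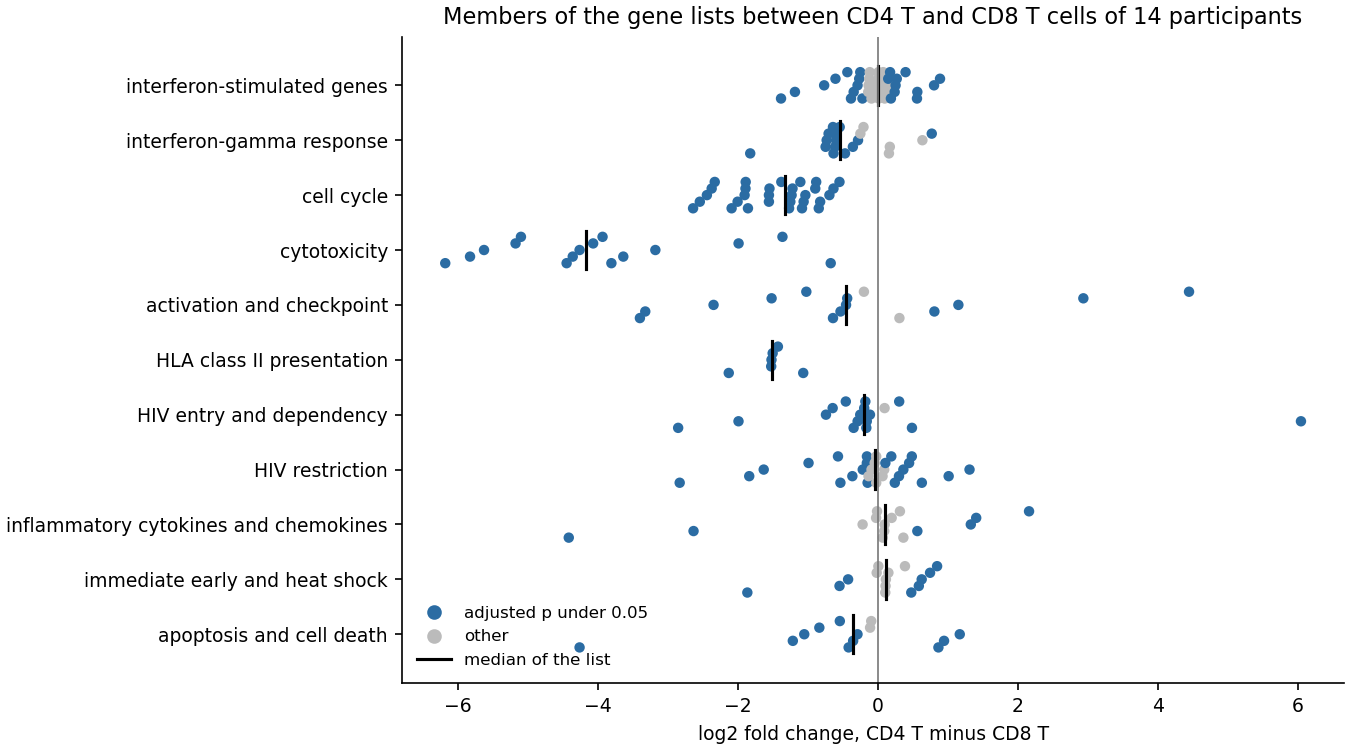
Log2 fold change of each measured list member, CD4 T minus CD8 T, over 14 participants, with the list median as a black line. Blue marks genes past the threshold when adjusted over all genes of the fit. Cytotoxicity genes lie lowest (median -4.16), and interferon-stimulated genes lie on both sides of 0 (median 0.01).

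The CD4-CD8- sort of O was set beside the CD4+ sort of the same person. KLRC1, a natural killer receptor, reached 80.2 CPM in the CD4-CD8- library against 0.0143 CPM (3 UMIs) in the CD4+ libraries, a ratio of 5588.5 (1908 to 27134.5), and KLRD1 had a ratio of 1107 (842 to 1484). LINC02446 (3455), KLRK1 (814), S100B (380), TYROBP (136), SYNGR1 (133), CD160 (99.2), FGR (95.4) and the gamma T cell receptor gene TRGC1 (83.8) followed. CD8A (ratio 378) and CD8B (151) also ranked there, and CD4 was 29.98-fold lower (5.51 against 165 CPM), but CD4 and CD8 proteins define the gate. IL2RA was 40.4-fold (1.24 against 49.95 CPM), TNFRSF4 21.97-fold, FOXP3 21.1-fold and CCR7 21.0-fold lower. WNT7A was 38.7-fold, F5 32.2-fold, TSHZ2 30.2-fold, MAL 26.5-fold, IFNGR2 23.4-fold, IL6R 22.03-fold and FMN1 18.1-fold lower. CD3D was near equal, at 498 and 511 CPM, while TRDC of gamma-delta T cells was 25.7-fold and ZBTB16 30.04-fold higher. CD14 and LYZ, monocyte genes, were at 0.124 and 0.619 CPM.

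All 16 cytotoxicity genes were over 2-fold higher in the CD4-CD8- library, with a median log2 ratio of 3.22 above all random lists. HLA class II (median 1.1, percentile 99.98) and inflammatory genes (0.45, percentile 99.5) also ranked high, as did cell cycle genes (0.41, percentile 100), though none of these 30 passed 2-fold. Interferon-stimulated genes ranked low (-0.28, percentile 0.01), as did activation genes (-0.34, percentile 0.36). Interferon-gamma response (0.13), HIV entry (0.06), restriction (-0.09), immediate early (-0.07) and apoptosis genes (0.13) lay at percentiles of 94.0, 74.3, 18.04, 38.1 and 88.2. Of 6444 genes with at least 20 CPM on 1 side, 310 were over 2-fold higher and 246 lower. There was 1 CD4-CD8- library, so no test was made, and intervals cover counting error only.

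The CD4+ sorts of O and P were set side by side over all cells kept. Cell cycle genes scored 4.70 ± 0.148 in O and 2.46 ± 0.356 in P (SD, 7 libraries each), where cycling T cells were 2129 of 34821 and 147 of 19443 cells. Cytotoxicity genes were lower in O (4.90 ± 0.0631 against 5.89 ± 0.0624), and of the 2696 cells of a cluster with GZMH, GNLY and NKG7 among its top genes 95.4% came from P. Scores were also lower in O for immediate early genes (6.95 against 7.56), inflammatory genes (1.96 against 2.48), restriction genes (6.36 against 6.60), interferon-stimulated genes (6.54 against 6.64) and interferon ligands (0.136 against 0.331). Activation genes (5.49 against 5.02), HIV entry genes (6.67 against 6.44) and apoptosis genes (5.85 against 5.77) were higher in O. Library ranges did not overlap for these 10 of 12 lists, and they overlapped for interferon-gamma response (4.68 and 4.74) and HLA class II (6.31 and 6.26). With only the cells that held a CD3 UMI, ranges did not overlap for 9 of 12 lists. Each side was 1 person, so no test was made, and shares of T cell subsets are not parted from changes within them.

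HIV RNA was counted cell by cell. In PBMC of F, 2.13% of CD4 T cells had at least 1 HIV UMI (173 of 8105, interval 1.83% to 2.47%, median depth 4443 UMIs). In B and NK cells, not usual targets of HIV, the share was 0.629% (0.385% to 0.970%, median 5595 UMIs) and 0.191% (0.0622% to 0.446%, median 4790.5 UMIs). CD8 T cells (0.665%) and CD14 monocytes (0.508%) lay within the interval of B cells, and MAIT cells reached 1.44%. Thinned to 2000 UMIs, the shares were 1.34% in CD4 T and 0.224% in B cells. Cells rich in HIV RNA numbered 66 in F, 35 of them in the CD4 T class, and held 88.6% of its HIV UMIs. In the other 13 participants 120 of 89617 cells had an HIV UMI (0.134%), with 0.202% in CD4 T (0.139% to 0.283%), 0.213% in MAIT (0.0976% to 0.405%), 0.259% in cycling T (0.112% to 0.510%), 0.329% in unnamed, 0.0749% in NK and 0.0783% in B cells. By participant the share reached 0.605% in A and 0.50% in B. None was seen in 6033 cells of I and 7912 of L, which allows a detected share of up to 0.0497% and 0.0379%.

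In the CD4-CD8- sort of O, 9.85% of cells had an HIV UMI (312 of 3169, 8.83% to 10.9%), against 2.97% in its CD4+ sort (1033 of 34821, 2.79% to 3.15%) and 0.674% in that of P. Within the CD4+ sort of O the share was 2.66% in CD4 T clusters and 12.03% in a cytotoxic cluster of 133 cells. Thinned to 2000 UMIs the shares in O were 5.30% and 1.37%. Every class of the CD4-CD8- library had such cells, including CD8 T (8.33%) and MAIT cells (7.76%), neither with a rich cell. Rich cells made up 2.15% of the CD4-CD8- library (68 cells, 1.67% to 2.71%) and 0.215% of the CD4+ sort of O (75 cells, 0.169% to 0.270%). They held 98.2% of the 16159 HIV UMIs of the CD4-CD8- library. Of its 204 cells in CD4 T clusters 48 were rich (23.5%). These clusters were named by the CD4+ gate, and their 141 cells without HIV UMIs in this library held CD4 RNA at 1.67 CPM. CD4 RNA stood at 229 CPM (183 to 284) in the 68 rich cells, with a CD4 UMI in 38 of them, and at 0.331 CPM in cells without HIV UMIs. In the CD4+ sort of O it was 242 CPM in rich cells and 160 CPM in cells without HIV UMIs.

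**Figure D5:**
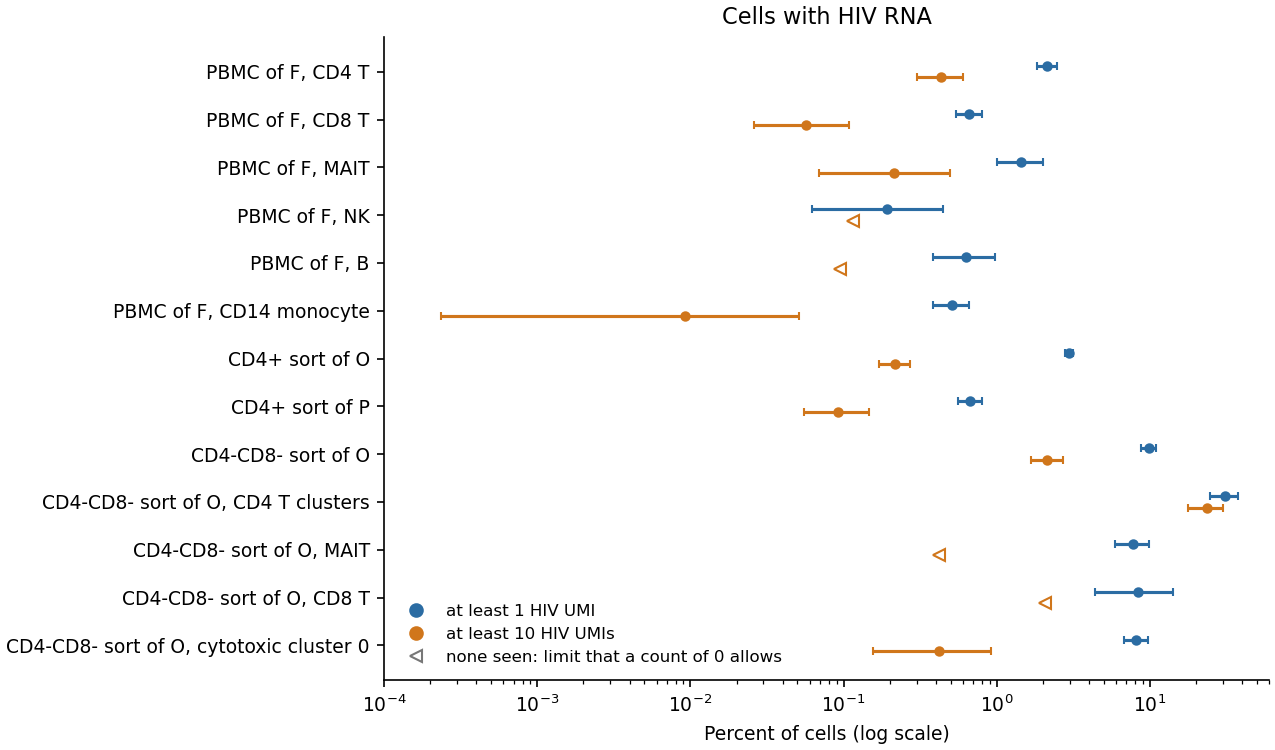
Percent of cells (log axis) with at least 1 (blue) or at least 10 (orange) HIV UMIs, with exact 95% intervals for counting error, and triangles at the limit that a count of 0 allows. Rich cells are 2.15% of the CD4-CD8- sort of O and 0.215% of its CD4+ sort.

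CD4 T cells with at least 1 HIV UMI were compared with those without in F, O and P. Of the 791 such cells of O 187 had 2 or more, and the share expected from free RNA was not measured in the CD4+ sorts, so an HIV UMI does not show that a cell was infected. Among genes with an average log2 CPM of at least 5, the most positive was GZMK (log2 fold change 1.2, SE 0.08, ENSG00000113088, GRCh38 chromosome 5, 55024253 to 55034570, plus strand), followed by GZMA (1.13) and CCL5 (1.0). CXCR3 (0.95), SYTL2 (0.90), BHLHE40 (0.78), MYBL1 (0.72), KLRB1 (0.72), LYAR (0.71), CTSH (0.69), PRF1 (0.67) and RGS2 (0.63) followed. TCEA3 (-1.14), ACTN1 (-1.13), CCR7 (-0.92, SE 0.09) and LEF1 (-0.62) were lower. AP3M2 (-0.89), TSHZ2 (-0.84), SESN3 (-0.76), HIST2H2AA4 (-0.75), EPHX2 (-0.69), PASK (-0.67) and SH3YL1 (-0.67) were also lower. As the naming rule required, these genes had the same direction in 3 of 3 participants. Against negative cells matched on cluster and UMI count their log2 fold changes had a median of 0.576 times these values, and 14 of the 24 chosen stayed past the threshold, with 4 under matching with 2 HIV UMIs and 6 with the cycling clusters.

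Of 18 measured HIV entry genes 4 were higher, among them the chemokine receptors CXCR6 (1.42), CXCR3 and CCR6 (0.30). Cytotoxicity had 6 higher and none lower of 16, with HOPX (0.99, but -0.028 without O), CST7 (0.58) and NKG7 (0.49) beside GZMA and PRF1. Activation had 4 higher of 15, with PDCD1 (0.73), TNFRSF18 (0.58) and LAG3 (0.52), and CD27 lower (-0.34). Of 28 restriction genes APOBEC3H (0.96) and SLFN5 (0.27) were higher and MORC2 (-0.72), SERINC5 (-0.51) and PTMA (-0.28) lower. GBP5 (0.42) and ICAM1 (0.86) were higher and SOCS1 (-0.35) lower of 20 interferon-gamma response genes, OASL (0.29) was higher of 39 interferon-stimulated genes, HLA-DMB (0.89) of 6 HLA class II genes and BBC3 (0.50) of 13 apoptosis genes. Immediate early genes had ATF3 higher (0.90) and DNAJB1 (-0.33), IER2 (-0.32), JUNB (-0.25) and HSPA6, near the floor, lower of 15. Of the list members called higher, HOPX, NKG7, CTSW, ICAM1, OASL, HLA-DMB, BBC3 and ATF3 were higher in only 2 of 3 participants. None of 30 cell cycle and 10 inflammatory genes passed in edgeR. With the cycling clusters included 51 genes were called, and PRF1, CST7 and NKG7 turned negative.

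The edgeR quasi-likelihood test called 429 of 13695 genes at the Benjamini-Hochberg threshold, 175 higher and 254 lower with HIV RNA. The balance turned with DESeq2 size factors (215 higher, 160 lower), without F (148 and 94) and without P (185 and 123). GZMK had an adjusted p of 3.23e-48 and CCR7 of 3.05e-19. Only 3 participants entered, so such small p-values rest on spread pooled over genes and do not measure how people vary. Adjusted over the list alone, the counts were 7 each for cytotoxicity, activation and restriction, 6 each for entry and immediate early, 4 for interferon-gamma response, 2 for interferon-stimulated, 1 each for HLA class II and apoptosis and 0 for cell cycle and inflammatory genes. Camera with the preset correlation gave adjusted p-values of 0.000355 for cytotoxicity, 0.0444 for activation and 0.0470 for HLA class II, none of which held with an estimated correlation (adjusted p = 0.455). The camera direction was up for interferon-gamma response and HIV entry genes, against medians just below 0, with preset adjusted p = 0.0562 for both. Fry passed no list here, with a lowest adjusted p of 0.452. Against negative cells matched on cluster and UMI count, a setting chosen after seeing the data, 49 genes were called, 45 of them among the 429, and DESeq2 called 61. Without participant O, who gave most positive cells, 45 were called, and 14 of the 24 genes chosen by the rule stayed past the threshold.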

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

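The search for far libraries was planned before the data were examined, and no test in this part was chosen after a result was seen. Among 32 groups of 7 libraries tested, 2 had a library far from the others, and chance gives about 1 in 20 such groups. In the CD4+ sort of O, 1 library had a median of 1.22% mitochondrial UMIs, against 1.27% to 1.30% in the other libraries. In the CD4+ sort of P, 1 library had an interferon-gamma response score of 4.67, against 4.73 to 4.77 in the others.

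The library of P with disagreeing labels, which was outside the planned comparisons, held 882 HIV UMIs, above the limit that a count of 0 allows, which each sorted library exceeded. Of its 697 cells 3 were rich in HIV RNA.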

How the results depend on the processing

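The automatic doublet threshold, the runs without the chip 2 participants, without naive and regulatory clusters and with CD3-positive cells or no doublet removal for O against P, and all alternatives of the HIV comparison except 2 HIV UMIs and doublet removal were chosen after seeing the data. Of the counts and shares that answer a comparison, 111 stayed close in size to the main value and 20 moved, with direction not compared. Of the others, 3282 stayed the same, 225 fell below the threshold, 39 passed it, 17 moved and 17 reversed. A change of sign where neither value passed the threshold was counted as the same. Except where construction shows it, the cause was not tested.

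Between CD4 T and CD8 T cells the count was 5203 with no replicate block, where IFI27, IFI44L, HSPA1B and FOS fell below the threshold. Leaving out each participant gave 6904 to 7690. Requiring an absolute log2 fold change of 1 left 1395 genes, a stricter rule by construction. Between participants DESeq2 called 21260 genes in all, with 3724 in CD4 T, 1469 in NK, 2011 in B and 6446 in CD14 monocyte cells. With no filter on low counts 54 of 59 list tests passed, against a larger background of genes. Second-chip participants alone gave 7 Pearson correlations past the threshold and no Spearman one (lowest adjusted p = 0.0612), with 6 people. A minimum of 50 CPM left 308 genes over 2-fold in the sorted libraries, with fewer eligible. The correlation of the plasmacytoid share was not run with other doublet rules.

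Cells with HIV RNA gave 124 genes with 2 HIV UMIs, 49 with matched negative cells, 11 with both, 51 with the cycling clusters, 61 with DESeq2, and 45 to 308 leaving out each participant (242 without F, 45 without O, 308 without P). DESeq2 size factors gave 375 genes, with 215 higher and 160 lower, against 175 and 254. At 2 HIV UMIs the shares were 0.839% of CD4 T cells of F, 3.12% of the CD4-CD8- sort, and 0.795% and 0.216% of the CD4+ sorts of O and P. Reversed with the cycling clusters were PRF1 (-0.092), CST7 (-0.013), NKG7 (-0.29) and CTSW (-0.35), and with 2 HIV UMIs and matched cells CD27 (0.016). Leaving out each participant gave -0.028 to 1.36 for HOPX and -0.12 to 0.54 for CTSW, the lowest without O.

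Without TMM, interferon-stimulated genes in CD14 minus CD16 monocytes turned to -0.14 and, in CD8 T minus NK cells, HIV restriction to -0.13 and apoptosis to -0.028. Without doublet removal, cytotoxicity turned to -0.52 in CD4 T minus B and -0.90 in CD4 T minus CD14 monocytes, and with the automatic threshold to -0.23 and -0.68. That threshold also turned interferon-stimulated genes in CD14 minus CD16 monocytes (-0.095). At resolution 2 cell cycle in CD8 T minus NK cells was -0.062. The interferon and inflammatory scores of CD14 monocytes correlated at -0.79 on the first chip. Simulated log2 changes of 0.5 were recovered least in the HIV comparison (17.5% of genes), in B (19.3%) and in NK cells (21.5%).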

Other observations

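The cluster comparison of monocytes, the CD4 RNA of rich cells in F, and the tests of free RNA, of random gate leakage, of depth and of chip 2 itself were chosen after the results were seen, as were the regroupings of samples for CD4 T cells, CD8 T cells, CD4 T against CD8 T cells and the HIV comparison.

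A small CD16 monocyte cluster, number 18, carried interferon RNA itself. Its 1308 cells held 65.7% of all IFNB1 UMIs in PBMC, at 269 CPM (260 to 278), where IFNB1 encodes interferon beta. The inflammatory CD14 monocyte cluster 19 had 39.6 CPM, the main CD16 cluster 10 had 1.56, and the CD14 clusters 9 and 8 had 0.574 and 0. Cluster 18 was also above them in CXCL10 (2023 CPM, against 495 in cluster 10 and 600 in cluster 19) and TNF (1616 CPM, against 83.2 and 639). IL1B stood at 6470 CPM there and at 7650 CPM in cluster 19, and IL6 at 598 and 492 CPM. The cluster made up 51.5% to 95.9% of CD16 monocytes in J to N and at most 5.26% in A to I. None of these genes entered the clustering, and they were chosen after their values were seen, and intervals cover counting error only. Counts were pooled over participants who fill these clusters unequally, so cluster and person are not told apart.

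In PBMC of F, 9 cells rich in HIV RNA lay in CD8 T clusters and held CD4 RNA at 506 CPM (366 to 681), against 9.65 CPM in CD8 T cells without HIV UMIs, and CD8 RNA at 706 against 2162 CPM. The library of P with disagreeing labels held CD14 at 289 CPM and LYZ at 2882 CPM, against 6.03 and 62.9 CPM in the CD4+ sort of P. Over all cells its CD4 RNA was 70.8 CPM against 158, TRDC 186 against 4.50, and KLRD1 249 against 3.22. That CD4 value pools in monocytes, whose sorted cluster itself held CD4 RNA at 158 CPM. In CD4 T clusters, cells without HIV UMIs held 3.90 CPM in this library (332 cells) and 153 CPM in the CD4+ sort. Of its 697 cells 435 had a CD3 UMI and 200 fell in the CD14 monocyte cluster. Against the CD4+ sort of P, its list medians were 1.64 for cytotoxicity, 2.03 for cell cycle, 3.26 for HLA class II and -0.75 for activation genes.

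For the genes that differ between participants the regroupings decide nothing, since only the real one leaves repeat captures of 1 sample as its residual spread and the others mix people into it. In 1 of 25 regroupings, the real one, as many genes were called in each class: 7334 against at most 77 in the others in CD4 T, 10879 against 17 in CD8 T, 4033 against 14 in NK, 4931 against 37 in B and 9911 against 713 in CD14 monocyte cells. For CD4 T against CD8 T cells 1 of 40 splits, the real one, gave 7491 genes and the others at most 0. That decides nothing either, since the classes came from clustering the expression of these same cells, and the other splits mix the cell types. For CD4 T cells with and without HIV RNA the 4 splits are too few for a share under 0.05, with 429 genes in the real split and at most 84 in the others.

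Low HIV UMI counts appeared in every cell type of the CD4-CD8- library. Free RNA from the rich cells is a candidate explanation: after thinning, cells with 1 to 9 HIV UMIs made up 3.28% of clusters without CD4 RNA and 3.36% of the other clusters, a ratio of 0.974 where a source in cells would differ between types. That contrast is weak, since cells without HIV UMIs in the CD4 T clusters of this library also held little CD4 RNA (1.67 CPM). Doublets with rich cells fall outside this range by definition, since a droplet with a rich cell would itself hold at least 10 HIV UMIs. The comparison of depth therefore cannot tell more. Cells with 1 to 9 HIV UMIs in clusters without CD4 RNA had 0.982 times the median total UMIs of those with none (5208 against 5306). No biological explanation was tested, and low-level infection of single cells stays open.

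Cells rich in HIV RNA were more frequent in the CD4-CD8- sort of O than in its CD4+ sort. CD4+ T cells passing the gate at random are argued against: among cells with a CD4 UMI, 38 of 43 were rich in the CD4-CD8- library and 48 of 17721 in the CD4+ libraries, a ratio of 326 (207 to 510). Deeper cells are argued against too, since after thinning to 2000 UMIs the ratio of shares with 5 or more HIV UMIs was 11.9 (8.03 to 17.5). The design names the sort as the difference, and a hypothesis is that infected CD4 T cells may lose CD4 protein from the surface while keeping CD4 RNA, which stood at 229 CPM in the rich cells of the CD4-CD8- library and 242 CPM in those of the CD4+ sort. Surface protein was not measured here, and the pattern rests on 1 person and 1 CD4-CD8- library. The library of P with disagreeing labels was left aside. Its rich cells were 3 of 697 (0.430%, 0.0889% to 1.25%), against 0.0926% (0.0549% to 0.146%) in the CD4+ sort of P, with overlapping intervals.

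Inflammatory genes of CD14 monocytes were high in several participants of the second chip, with scores of 5.94 to 10.95 against 3.76 to 6.01 on the first. The chip itself is argued against, because the libraries of F on the second chip differed from its others by -0.0171, which is -0.00417 of the difference of 4.11 between the chips' participants. Activation of all cells during handling cannot be told apart: immediate early genes of CD4 T cells correlated with the inflammatory score at rho = -0.292 over 14 participants (permutation p = 0.309), with 0.595 on the first chip and -0.314 on the second. Sample handling before loading is not given in the labels and may differ between the chips' participants. No biological explanation was tested, since the labels give none.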
